A study of Glycine max with 12 samples.

How the data were processed

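Roots of the soybean cultivar Enrei were sampled, per the labels, after 6 weeks in a glasshouse in pots that received nothing (control), 1 ml of a suspension of Bradyrhizobium diazoefficiens, 200 spores of Gigaspora rosea, or both, and 3 of 5 independent biological replicates per treatment were hybridized. Each of the 12 arrays took 500 ng of RNA labelled with 1 dye and lay on a slide of its own. The scanner files hold intensity values that, per the file headers, Agilent Feature Extraction 9.1.3.1 produced from 44290 spots by subtracting background and detrending, without scaling between arrays, so that values may be negative. The same files hold raw mean spot and local background intensities and 0 or 1 marks for spots well above background, saturated or uneven, set by that software per the file headers.

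The authors also deposited a table with a single value per probe and array, which is a ratio: the processed signal over the 75th percentile of its array, with values under 0.01 set to 0.01, on a linear scale and not centred per probe. This was worked out from the values, since the labels do not state it; none of scale, centring or direction stays unknown. Column medians of the table were 0.282, 0.224 and 0.261 for control, 0.251, 0.196 and 0.217 for rhizobium, 0.177, 0.185 and 0.183 for AM, and 0.187, 0.184 and 0.191 for dual. The AM and dual columns matched the scanner file of their own replicate for 100% of probes. The 3 control and the 3 rhizobium columns each matched, for 100% of probes, the file of another replicate of the same group (own file 8.43 to 15.8%), so replicate numbers in these groups are doubtful, and group membership is not touched. The scanner files were used.

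The main values are log2 of the processed signal over the array's 75th percentile, floored at 0.01, for the 42034 non-control probes, each with 1 spot. The 156 spots marked as uneven were set to missing. Probes well above background on all 3 arrays of at least 1 group were kept (33406; 33404 where the dual group enters). Limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0 and version 1.17.8 of data.table) fitted 4 group means to the 12 arrays, and the 5 comparisons and the interaction were tested by moderated statistics with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Changes on the log2 scale are given with their SE. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

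No probe matched the supplied gene table and no genome was supplied. Names are those of the probe descriptions in the deposited array annotation, which for many probes describe the best match in another plant. Of the kept probes, 16727 had a description that names a function. Several probes may stand for 1 gene, and no coordinates are given.

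A probe counts as below detection in a group when none of its 3 arrays is well above background. Its fold is then written as "at least": the mean of the brighter group minus, for each array of the dim group, the larger of the measured value and the lowest signal that the scanner called well above background on that array. Such bounds are not ranked. Where some arrays of the dim group were above background, their number is given.

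Gene lists (35, chosen by words in the descriptions) were fixed before the data were examined, as were the comparisons, the tests, most other ways of processing and the rule for naming genes. They cover leghemoglobins, nodulins, symbiosis signalling, purine and ureide synthesis, ammonium assimilation, carbon supply to nodules, phosphate transporters, phosphate starvation, ammonium transporters, nitrate uptake and reduction, AM-associated genes, fatty acid synthesis, the carotenoid and strigolactone pathway, protease inhibitors, proteases, defence, isoflavonoids and phenylpropanoids, class III peroxidases, aquaporins, sugar transport, starch metabolism, auxin, cytokinin, ethylene, gibberellin, jasmonate and lipoxygenase, iron and nicotianamine, lectins, cell cycle and histones, ribosomal proteins, photosynthesis (green tissue), seed storage (cotyledon), vegetative storage, heat shock and dehydration. The 34 lists with at least 5 tested probes were tested with camera at a preset correlation between genes of 0.01, adjusted over all lists and comparisons, with camera at an estimated correlation as the stated check and fry as an alternative. Kept probes with a missing spot (122) were left out of the list tests.

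Named genes follow a rule: per comparison of 2 groups the 10 largest rises and 10 largest falls among called probes whose arrays do not overlap and whose description names a function, 1 probe per description; for the interaction 5 each way; and per list up to 4 called members with the largest change, or the brightest member where none was called. Some that the rule names are left out of the text for length.

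The tests were tried on data simulated at the spread of these arrays. With 200 of 33406 probes changed, limma called 0% to 6.5% of 2-fold, 60% to 67.5% of 4-fold and 91.5% to 92.5% of 16-fold changes in the 5 comparisons of groups, and 0%, 30.5% and 77% for the interaction. The share called depends on how many probes change. These values therefore do not carry over to the comparisons in which 7259, 11767 and 11798 probes passed.

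Other ways of processing chosen at the same time were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a strict filter (22186 probes well above background on all 12 arrays), uneven spots kept, the deposited value table, an adjusted p under 0.01, a fold of at least 2, an intensity trend with robust prior, separate fits of the 2 groups, the replicate number as a block, the scan session as a block, and leaving out each array. Added after the data were seen were a floor of 0.25, an offset of 0.25 added before the log2, each of these without control 3, quantile normalization of the kept probes alone, and fits within scan 2 and within scan 3. The numbers were tested for pairing by the correlation of probe values, centred within groups, between arrays with the same replicate number. For control and rhizobium these were 0.16 to 0.31 and for control and dual 0.11 to 0.26, above 0.1 in all 3 pairs, so values with the replicate block are given where they move a count by more than 1.5 times or a list across the threshold. In the other pairs of groups they were not above 0.1 throughout (control and AM -0.09 to 0.04, rhizobium and dual 0.03 to 0.25, AM and dual -0.1 to 0.16).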

Results

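Transcript levels were measured in roots of the soybean cultivar Enrei grown in a glasshouse for 6 weeks after 4 treatments: no inoculation (control), a rhizobium (Bradyrhizobium diazoefficiens, a bacterium that fixes nitrogen in root nodules), an arbuscular mycorrhizal (AM) fungus (Gigaspora rosea, a soil fungus that grows inside root cells), or both together (dual). Each group had 3 one-colour arrays, 1 per biological replicate, and each array carried 42034 soybean probes. The share of probes well above background lay between 80.1% and 86.6% on the control arrays, 62.9% and 78.3% with rhizobium, 62.6% and 65.4% with the AM fungus, and 67.3% and 71.2% with both. The 75th percentile of the background-subtracted intensity ran from 149 on the rhizobium 3 array to 394 on the dual 2 array. The number of arrays, 3 per group, limits the precision of every fold change. Correlations between replicates across probes, which are not independent replicates, lay between 0.946 and 0.965 for control, 0.901 and 0.943 for rhizobium, 0.971 and 0.981 for AM, and 0.973 and 0.979 for dual. The first principal component held 54.9% of the variance and separated the 6 arrays with the fungus from the 6 without. On the second (18.2%) the rhizobium 3 array lay at -196.1, with every other array between -27.5 and 77. The arrays were scanned in 3 sessions. Scan 1 held control 2 and 3, scan 2 held control 1, rhizobium 1 and 2 and AM 1 and 2, and scan 3 held rhizobium 3, AM 3 and the 3 dual arrays. With the scan as a block, control 2 and 3 only set the level of scan 1. Each blocked value that uses control therefore rests on control 1 alone, and dual reaches it only through rhizobium and AM arrays. A fit within scan 2 or scan 3 leaves a group of 1 array, whose spread is taken from the other groups. Values below are log2 fold changes ± SE from limma with its Benjamini-Hochberg adjusted p, n = 3 arrays per group. "At least" marks a fold against a group in which the probe was not well above background on any array.

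The level of nodule transcripts on each array checks the labels of the control and rhizobium groups. Over 23 nodule probes (leghemoglobins and nodulins that rose in dual against AM roots, so the levels of those groups follow from the choice and check no label), the mean of the array medians was -2.67 ± 1.93 for control (log2 of signal over the 75th percentile, SD, n = 3), 1.24 ± 0.81 for rhizobium, -6.05 ± 0.98 for AM and 3.1 ± 1.01 for dual. The control 3 array stood at -0.45, against -3.73 and -3.85 on the control 1 and 2 arrays, and below the 3 rhizobium arrays at 0.80, 2.17 and 0.74. Control 3 thus carried more nodule transcript than the other controls, and some nodule probes, nodulin C51 (GMFL01-10-C23-R_647) and leghemoglobin GMFL01-15-A01-R_273 among them, were well above background on all 3 control arrays. Each nodule value against control below rests on that group, except with the scan as a block or within scan 2, where it rests on control 1 alone.

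**Figure D1:**
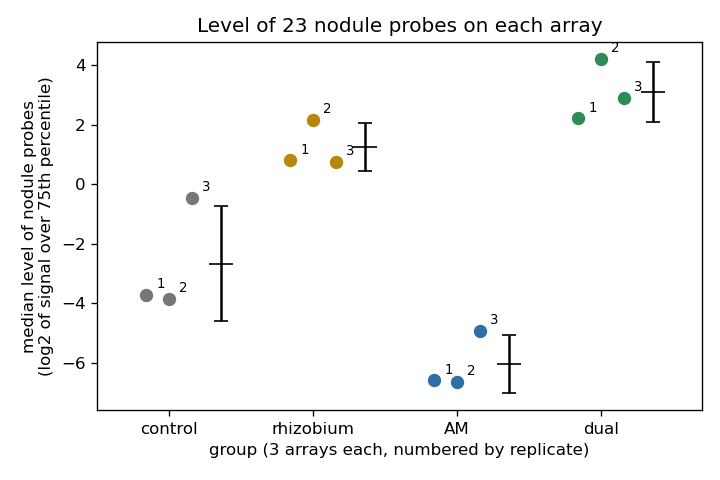
Median level of 23 nodule probes on each array (y axis, log2 of signal over the array's 75th percentile) by group (x axis), with replicate numbers beside the points and the mean ± SD of the 3 array medians as black bars. The control 3 array lies at -0.45, above the control 1 and 2 arrays (-3.73 and -3.85) and below the 3 rhizobium arrays (0.74 to 2.17), while the dual arrays lie between 2.21 and 4.20.

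The comparison of rhizobium with control roots asks which transcripts nodulation alone changes. A small set of transcripts first described in nodules rose. Nodulin C51 (probe GMFL01-10-C23-R_647) rose by 5.25 ± 0.87 (adjusted p = 0.038), the early nodulin GmN315 (CO978789.1_581) by 5.01 ± 0.81 (adjusted p = 0.036, control well above background on 2 of 3 arrays) and ENOD40-2 (GMFL01-40-F18-R_321), a regulatory transcript of the early nodule, by 3.51 ± 0.56 (adjusted p = 0.035). The largest named rise was that of a probe described as a poplar nitrate transporter (BQ613046.1_186), at 6.95 ± 0.69 (adjusted p = 0.0025), with control well above background on 1 of 3 arrays. Asparagine synthetase 1 (BI946107.1_266), which makes the transport amide asparagine, fell by 2.09 ± 0.35 (adjusted p = 0.040). The other named rises were a CPRD49 homolog (GMFL01-49-I04-R_363, 3.85), a plastid sugar phosphate antiporter (AW761153.1_277, 2.82, control well above background on 2 of 3 arrays), a type 1 metallothionein (GMFL01-41-H18-R_362, 2.12), a cinnamoyl-CoA reductase homolog (GMFL01-24-I22-R_462, 2.12), a basic helix-loop-helix factor (CA785478.1_634, 1.93) and a defence-related SCP-domain protein (CO985321.1_478, 1.66). The named falls apart from asparagine synthetase were dim: an AAA-type ATPase (AW185464.1_481) fell at least 2.38-fold, a splicing factor (AW472155.1_547) at least 2.49-fold, a DTW-domain protein (BG790927.1_451) at least 2.12-fold and a TINY-like transcription factor (CX710923.1_596) at least 1.51-fold. Mitotic cyclin a2 (AW756565.1_386, at least 1.36-fold), a late embryogenesis abundant protein (CK605689.1_715, at least 1.74-fold) and the photosystem protein psbC (BI674351.1_441, at least 1.45-fold) fell in the same way. Under normexp background correction the values of cyclin a2, the late embryogenesis abundant protein and the TINY-like factor changed sign. With the scan as a block the named rises kept their direction and did not pass, the nitrate transporter at 8.03 (adjusted p = 0.063), GmN315 at 7.14 (0.063), nodulin C51 at 6.06 (0.24) and ENOD40-2 at 3.99 (0.22). Of the named falls the AAA-type ATPase passed (adjusted p = 0.010) and asparagine synthetase did not (-1.93, 0.35). With the replicate number as a block ENOD40-2 (adjusted p = 0.051), CPRD49 (0.052), the basic helix-loop-helix factor (0.051), the late embryogenesis abundant protein (0.062) and psbC (0.064) did not pass.

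The nodulation lists were higher as groups with rhizobium, by camera with a preset correlation. The 9 leghemoglobin probes, the oxygen carriers of the nodule and the enzymes that reduce them, had a mean log2 change of 2.58 (camera adjusted p = 4.6e-05). None passed among all probes, while 6 were higher and 1 lower adjusted over the list alone. Of 58 nodulin probes 3 rose and none fell (17 higher and 3 lower adjusted over the list alone), with a mean of 0.99 (adjusted p = 6.3e-05). The 24 symbiosis signalling probes had a mean of 0.58 (adjusted p = 0.00047) with none past the test. The 427 ribosomal protein probes were higher relative to other probes with a mean of only 0.04 (adjusted p = 8.9e-05). The 34 seed storage probes (mean -0.80, adjusted p = 0.018, none past the test) and the 114 photosynthesis probes (mean -0.57, adjusted p = 0.030, 1 fall) were lower. None of these list calls held with an estimated correlation, where each had adjusted p = 0.98 with an estimated correlation. With the scan session as a block, leghemoglobins (mean 3.31, adjusted p = 0.00014), nodulins (1.51, 7.7e-06), ribosomal proteins (0.32, 9.8e-16) and seed storage (-0.84, 0.011) still passed. Symbiosis signalling (0.63, adjusted p = 0.071) and photosynthesis (-0.44, adjusted p = 0.20) did not. Within scan 2, with 1 control array, the means were 3.54, 1.73 and 0.74 for leghemoglobins, nodulins and symbiosis signalling, 0.33 for ribosomal proteins, -0.67 for seed storage and -0.28 for photosynthesis, the last not past the test (adjusted p = 0.34). Neither passed with quantile normalization (-0.09, adjusted p = 0.77, and -0.26, 0.45), and under normexp background correction both means turned to 0.11. Nodulins did not pass on the probes well above background on every array (mean 0.34, adjusted p = 0.37), a filter that leaves too few leghemoglobin probes to test.

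Among 33406 probes tested with rhizobium against control, 120 passed in limma, 20 higher and 100 lower, with 6036 at an unadjusted p under 0.05. Of the 100 falls 93 lay among the 11136 probes with the lowest signal, while the 11135 brightest held 9 rises and 1 fall. The 3 and 3 arrays did not overlap for 18.4% of probes, where chance gives 10%. The median log2 change of all probes was -0.15, against -0.01 under quantile normalization and 0.06 under median scaling, and changes are relative to it. The count depended on the scaling: 40 passed (23 higher, 17 lower) with quantile normalization and 57 (22 and 35) with median scaling. It was 4 with normexp background correction, under which 50% of the 120 calls kept their direction. With the strict filter, and in a separate fit of the 2 groups, it was 0, and with an offset of 0.25 it was 2. Blocking on the scan left 4, all lower, and within scan 2 none did. Scan 2 holds 1 control array. With the replicate number as a block 191 passed (18 higher, 173 lower). The count fell to 40 without control 1, 53 without control 2, 79 without AM 1, 71 without AM 2, 67 without dual 1 and 77 without dual 2. It rose to 189 (50 higher, 139 lower) without control 3, the control array with the most nodule transcript, and to 1118 without rhizobium 1.

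The comparison of AM with control roots asks which transcripts the fungus alone changes, and the response was broad. A serine carboxypeptidase (BE657431.1_593), a protease family long known from mycorrhizal roots, rose at least 3620-fold (adjusted p = 4.4e-11), and 3 further serine carboxypeptidase probes rose by 7.92 ± 0.20 (BG157125.1_279), 7.47 ± 0.24 (CO985404.1_587) and 6.39 ± 0.31 (BQ133714.1_429). Of the 33 probes that share the description of CO985404.1_587, 9 rose and 3 fell. The poplar nitrate transporter homolog (BQ613046.1_186) rose by 9.88 ± 0.69 (adjusted p = 8.3e-06, control well above background on 1 of 3 arrays), and a PAR-1c homolog (CA784467.1_396) at least 714-fold. Some enzymes that build fatty acids in plastids rose (14 of 40 probes, with 8 lower), among them the biotin carboxyl carrier subunit accB-2 (GMFL01-28-C14-R_202) by 5.11 ± 0.26 (adjusted p = 1.2e-06) and an acyl carrier protein (GMFL01-20-M03-R_498) by 5.07 ± 0.20 (adjusted p = 2.6e-07). Probes of the auxin-conjugating GH3 family rose by 7.69 ± 0.38 (BU547810.1_499) and 5.44 ± 0.23 (AW185677.1_394), while of all 123 auxin probes 6 rose and 49 fell (camera adjusted p = 0.30). Kunitz trypsin inhibitors, which block digestive proteases, fell on the named probes, KTi3 (GMFL01-04-A06-R_303) at -4.30 ± 0.64 (adjusted p = 0.00054) and trypsin inhibitor B (GMFL01-43-F10-R_200) at -4.34 ± 0.71 (adjusted p = 0.00099). Of all 29 protease inhibitor probes 3 rose and 16 fell, and the list did not pass camera (adjusted p = 0.096).

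The other large rises with the fungus were a subtilisin-type protease like cucumisin (BI971063.1_675, 6.66 ± 0.52; of the 7 probes with its description 1 rose and 3 fell), probes for annexins, which are calcium-binding membrane proteins (CD418071.1_393, 7.35 ± 0.48, the only call among 4 with its description, and GMFL01-37-K06-R_277, 7.09 ± 0.49), a LysM-domain protein (CA852392.1_521, 6.83 ± 0.83) and a putative DNA-binding protein (CX711554.1_589, 7.55 ± 0.40). Carbonic anhydrase, which interconverts carbon dioxide and bicarbonate, rose on the named probes, by 7.57 ± 0.60 (GMFL01-22-L20-R_541, control well above background on 2 of 3 arrays), 6.20 ± 0.43 (GMFL01-17-A06-R_196) and 5.08 ± 0.41 (BU084084.1_519), while the list that holds it, carbon supply to nodules, had 13 rises and 21 falls of 79 (camera adjusted p = 0.65). Falls of named transcripts included those of the win gene of the wound response (BI969385.1_651, at least 36.3-fold), a WRKY-type factor (CO984852.1_614, at least 11-fold), a light-harvesting protein (BM177394.1_481, at least 8.75-fold) and photosystem protein psbX (BI424207.1_81, at least 8.26-fold). A lipoxygenase (BU545735.1_564) fell at least 6.68-fold, a peroxidase (BI893626.1_470) at least 6.36-fold and isoflavone synthase 1 (BI787856.1_499), which opens the isoflavonoid branch, at least 5.94-fold. The win call (adjusted p = 0.025) did not hold with quantile normalization (0.082), the scan as a block (0.11), or without control 1 (0.091), control 3 (0.088), AM 1 (0.071) or AM 3 (0.072).

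Of 40 fatty acid synthesis probes 14 rose and 8 fell with the fungus (17 and 9 adjusted over the list alone), with a mean of 0.56 (camera adjusted p = 2.2e-05). A second acyl carrier protein probe (GMFL01-15-B05-R_435) rose by 4.02 ± 0.20, while an acetyl-CoA carboxylase probe (AW830581.1_505) fell at least 3.09-fold. None of 75 jasmonate and lipoxygenase probes rose and 31 fell (mean -1.21, adjusted p = 0.028), among them lipoxygenase-2 (AW279131.1_363, at least 3.15-fold). Photosynthesis (2 rises and 71 falls of 114, mean -1.87, adjusted p = 1.9e-06) and seed storage probes (2 rises and 24 falls of 34, mean -2.0, adjusted p = 0.00047) were lower, with beta-conglycinin subunits down at least 6.53-fold (AW317783.1_474) and at least 3.53-fold (AI940988.1_472). Ribosomal proteins were called higher relative to other probes (adjusted p = 0.0018) with a mean of -0.32, a median of 0.22, and 51 rises and 95 falls among 427. None of these calls held with an estimated correlation, at adjusted p = 0.98 with an estimated correlation. With the scan as a block fatty acid synthesis (mean 0.59, adjusted p = 0.00014), ribosomal proteins (-0.04, 1.6e-07), photosynthesis (-1.74, 0.00015) and seed storage (-2.04, 0.0019) passed, and jasmonate and lipoxygenase did not (-1.04, adjusted p = 0.17). Within scan 2, with 1 control array, the means were 0.55, -0.06, -1.91, -2.21 and -1.11 in that order, the last not past the test (adjusted p = 0.093). Photosynthesis did not pass on probes well above background on every array (mean -0.11, adjusted p = 0.87) nor with a floor of 0.25, where its mean was -0.03. The seed storage mean turned to 0.16 with that floor, and the list did not pass under normexp (-0.14, adjusted p = 0.28). Ribosomal proteins did not pass with quantile normalization (adjusted p = 0.28).

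Several groups tied to the partnership moved both ways with the fungus and did not pass as lists. Of 18 phosphate transporter probes 2 rose and 5 fell (mean -0.54, adjusted p = 0.96), among them one described as mitochondrial (BM094791.1_479), which fell by 2.94 ± 0.65 (AM well above background on 2 of 3 arrays), and one (CF805923.1_567), which fell by 2.34 ± 0.39. Of 59 phosphate starvation probes 5 rose and 16 fell (adjusted p = 0.69): one purple acid phosphatase (BU548367.1_507) rose by 5.09 ± 0.73 and another (BM308467.1_508) fell at least 4.51-fold. Of 15 AM-associated probes 2 rose and 7 fell (adjusted p = 0.48), with one acyl-ACP thioesterase (GMFL01-23-D20-R_480) up by 3.34 ± 0.37 and another (BF425342.1_540) down at least 3.25-fold. Nitrate uptake and reduction had 3 rises and 3 falls among 18 (adjusted p = 0.99), the rises including a nitrate transporter (BM177075.1_485, at least 20.7-fold) and the high-affinity transporter NRT2 (GMFL01-19-H08-R_500, 3.73 ± 0.71). Of 7 probes described as ammonium transporters 2 fell (adjusted p = 0.99). One of them carries the name SAT1 (AW277879.1_575, -2.90 ± 0.28, AM well above background on 1 of 3 arrays), and its function is taken from the probe description alone. Leghemoglobins had no rise and 5 falls among 9 (mean -2.67, adjusted p = 0.10), with GMFL01-15-A01-R_273 at -4.61 ± 0.96 (AM on 1 of 3) and GMFL01-23-B02-R_31 down at least 4.74-fold, against a control group that includes control 3. Of 58 nodulin probes 7 rose and 16 fell (mean -0.57 where camera pointed up, adjusted p = 0.74), with nodulin-26 (GMFL01-10-D07-R_576) up by 5.43 ± 1.33 (control on 1 of 3).

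In AM against control roots 11767 of 33406 probes passed in limma, 2629 higher and 9138 lower, and 9214 of them changed by at least 2-fold. The arrays did not overlap for 53.3% of probes (10% by chance). The excess of falls went with brightness and scaling. Among the 33.3% of probes with the lowest signal 95.2% of the calls were falls and among the brightest 33.3% of probes 35.4% were, with 1545 rises and 845 falls. Quantile normalization gave 9370 calls (3985 higher, 5385 lower) and median scaling 12119 (6689 higher, 5430 lower). The median of all probes moved from -0.31 in the main scaling to -0.08 and 0.18. Blocking on the scan left 7498 probes (1831 higher, 5667 lower). Within scan 2, which sets 2 AM arrays against 1 control array, 64.7% of all probes were lower with the fungus.

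**Figure D2:**
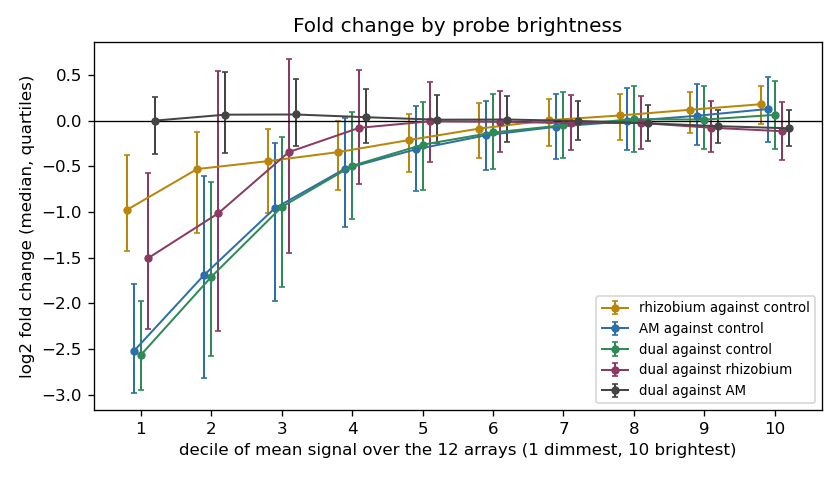
Log2 fold change (y axis; points are medians, bars the quartiles) in 10 bins of the 33406 probes by mean signal over the 12 arrays (x axis) for the 5 comparisons of groups. In the dimmest bin the median was -2.52 for AM against control and -2.57 for dual against control, and in the brightest 0.13 and 0.06.

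The comparison of dual with control roots asks what both microbes change together, and it held the rises of both partners. From the nodule side, nod24 (CO978758.1_684), a protein of the membrane around the bacteria, rose by 9.16 ± 1.94 (adjusted p = 0.0048), a nodulin (GMFL01-19-F21-R_322) by 8.88 ± 1.44 (adjusted p = 0.0011), leghemoglobin (GMFL01-02-G04-R_389) by 8.72 ± 1.44 (adjusted p = 0.0012) and nodulin C51 (GMFL01-10-C23-R_647) by 7.03 ± 0.87 (adjusted p = 0.00024). From the fungal side, the serine carboxypeptidase (BE657431.1_593) rose at least 1950-fold and GH3 (BU547810.1_499) by 6.61 ± 0.38 (adjusted p = 3.9e-06). The nitrate transporter homolog (BQ613046.1_186), which rose with each single microbe, rose by 9.68 ± 0.69 (adjusted p = 1.4e-05). Glutamine synthetase (GMFL01-34-N19-R_431), which takes up fixed ammonium, rose by 6.29 ± 1.42 (adjusted p = 0.0064), and asparagine synthetase (GMFL01-15-J13-R_221) fell by 3.47 ± 0.76 (adjusted p = 0.0055). Control was well above background on 1 of 3 arrays for nod24, nodulin GMFL01-19-F21-R_322 and the nitrate transporter, and on 2 of 3 for leghemoglobin and glutamine synthetase.

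Further nodule transcripts that rose in dual roots were nodulin-26 (GMFL01-10-D07-R_576, 7.96 ± 1.33), a channel of the same membrane, nodulin E27 (GMFL01-22-I02-R_554, 7.46 ± 1.15) and GmN315 (CO978789.1_581, 7.03 ± 0.81). The nodulin-26 probe stood about as high with the fungus alone (mean log2 level 1.36) as with rhizobium alone (1.49), so its rise is not particular to nodulation. A carbonic anhydrase of soybean (GMFL01-16-O23-R_345) rose at least 41.5-fold and a nodule inception homolog (GMFL01-11-D19-R_274), a transcription factor of nodule formation, by 6.31 ± 1.54. Control was well above background on 1 of 3 arrays for nodulin-26, E27 and the nodule inception homolog, and on 2 of 3 for GmN315. Falls included a peroxidase (CA801119.1_687, at least 11.1-fold), nitrite reductase (BG155089.1_555, -4.51 ± 0.78, dual well above background on 1 of 3 arrays), nitrate reductase (BG551225.1_311, -4.08 ± 1.02, dual on 2 of 3), Mcp20 (GMFL01-11-K04-F_424, -4.60 ± 0.81), the photosystem protein psaD (BQ133905.1_20, -4.04 ± 0.55, dual on 1 of 3) and the cyclin-dependent kinase CDKB (CD402746.1_508, at least 5.78-fold). The nitrate reductase fall did not pass with median scaling (adjusted p = 0.067). With the scan as a block glutamine synthetase (10.63, adjusted p = 0.013), the leghemoglobin (11.05, 0.021) and the nodulins, from GmN315 (9.45, 0.0032) to nod24 (11.46, 0.046), passed. The nodule inception homolog (8.04, adjusted p = 0.091), nitrate reductase (-2.40, 0.23) and asparagine synthetase (-2.33, 0.26) did not.

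Of 9 leghemoglobin probes 6 rose in dual roots and none fell (mean 4.04, camera adjusted p = 0.00027), and of 58 nodulins 25 rose and 9 fell (1.71, 1.6e-06). Of 24 symbiosis signalling probes 6 rose and 5 fell (0.46, adjusted p = 0.032), of 40 fatty acid synthesis probes 18 rose and 7 fell (0.65, 1.6e-06), with accB-2 (GMFL01-28-C14-R_202) up by 4.69 ± 0.26. Ribosomal proteins were higher relative to other probes (131 rises, 91 falls, mean -0.11, median 0.49, adjusted p = 3.1e-07), and so were cell cycle and histone probes (25 rises, 28 falls of 111, mean -0.19, median 0.00, adjusted p = 0.047). Photosynthesis (1 rise, 75 falls, mean -1.81, adjusted p = 1.1e-06) and seed storage (1 rise, 25 falls, -2.08, 0.00016) were lower. These list calls had adjusted p = 0.98 with an estimated correlation. In the fit with the scan as a block the means were 4.57 for leghemoglobins, 2.60 for nodulins, 0.64 for fatty acid synthesis, 0.15 for ribosomal proteins, 0.20 for cell cycle, -1.36 for photosynthesis and -1.87 for seed storage, all past the test, and 0.48 for symbiosis signalling, which was not (adjusted p = 0.36; 0.16 with quantile normalization). Cell cycle did not pass with the replicate number as a block (adjusted p = 0.051) or with quantile normalization (0.051). Nodulins did not pass on probes well above background on every array (mean 0.63, adjusted p = 0.10), nor did photosynthesis (-0.31, adjusted p = 0.46). Of 50 ammonium assimilation probes 8 rose and 24 fell (mean -0.73, adjusted p = 0.68).

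In dual against control roots 11798 of 33404 probes passed in limma, 2663 higher and 9135 lower, and 54.7% of probes did not overlap between arrays (10% by chance). Falls made up 94.8% of the calls among the 11136 probes with the lowest signal and 40.8% among the 11135 brightest. Quantile normalization gave 9340 calls (4123 higher, 5217 lower) and median scaling 11348 (6123 higher, 5225 lower). The median of all probes was -0.30, -0.08 and 0.14 under the 3 scalings. Blocking on the scan left 4363 (1202 higher, 3161 lower). Dual and control arrays shared no scan, so the blocked fit reaches control 1 only through rhizobium and AM arrays, and no value within a scan can be given.

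**Figure D3:**
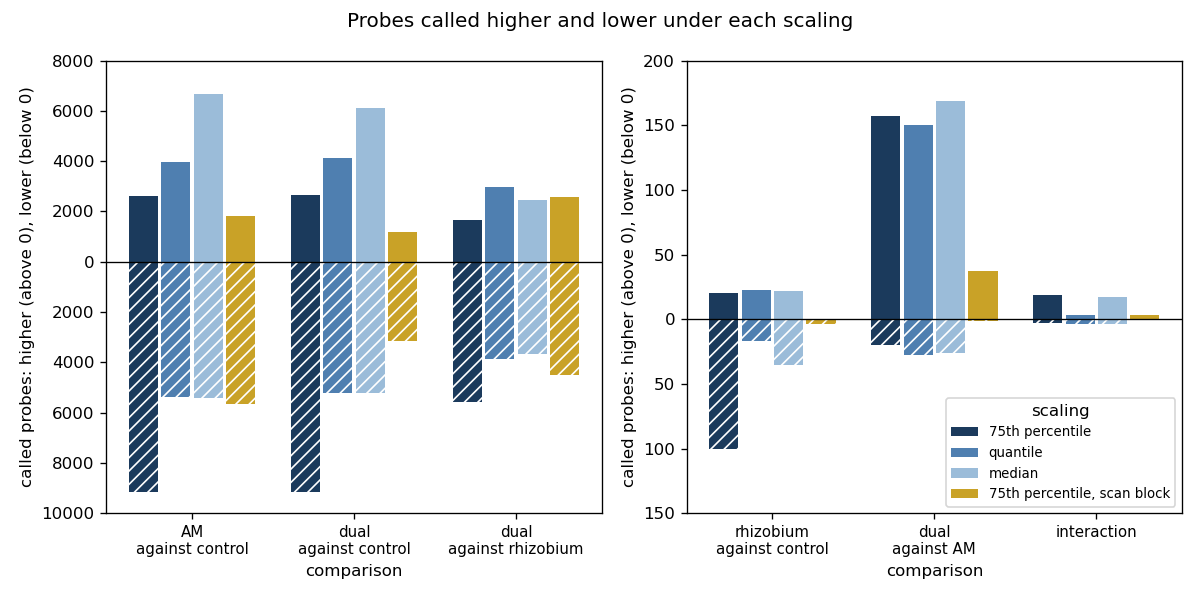
Number of probes called higher (plain bars, above 0) and lower (hatched bars, below 0) in limma at adjusted p under 0.05 (y axis) for each comparison (x axis) under 3 scalings of the arrays and with the scan session as a block, the left and right panels on different scales. For AM against control, falls outnumber rises with the 75th percentile (9138 and 2629), and rises outnumber falls with the median (6689 and 5430).

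The comparison of dual with rhizobium roots asks what the fungus adds to nodulated roots. The same serine carboxypeptidase (BE657431.1_593) rose at least 1500-fold (adjusted p = 8.7e-11), a zeatin O-glucosyltransferase (GMFL01-27-L14-R_395), which stores the hormone cytokinin, at least 60.7-fold, a germin-like protein (CO983251.1_585) by 6.66 ± 0.42 (adjusted p = 6.7e-06) and GH3 (BU547810.1_499) by 6.36 ± 0.38 (adjusted p = 5.2e-06). Some nodule transcripts were higher than with rhizobium alone (2 of 9 leghemoglobin and 4 of 58 nodulin probes, with 3 nodulins lower): leghemoglobin probes by 2.10 ± 0.46 (GMFL01-23-B02-R_31, adjusted p = 0.0084) and 2.07 ± 0.62 (GMFL01-11-O02-R_23, adjusted p = 0.036). Glutamine synthetase (GMFL01-09-P04-R_499) rose by 2.69 ± 0.39 (adjusted p = 0.00076), while of 50 ammonium assimilation probes 2 rose and 10 fell. The lectin Le2 (GMFL01-20-M10-R_482) fell by 4.60 ± 0.69 (adjusted p = 0.00098, dual well above background on 1 of 3 arrays). Named probes for chalcone synthase, which opens flavonoid synthesis, fell at least 5.64-fold (GMFL01-01-J24-F_240) and at least 3.32-fold (BE021269.1_486).

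The further rises with the fungus in nodulated roots were a serine carboxypeptidase (CO985404.1_587, 6.94 ± 0.24; of the 33 probes with its description 8 rose and 2 fell), an annexin (CD418071.1_393, 6.80 ± 0.48), PAR-1c (CA784467.1_396, 6.80 ± 0.87, rhizobium well above background on 1 of 3 arrays), a daidzein O-methyltransferase (BU091459.1_251, at least 23-fold; of 6 with its description 1 rose and 1 fell), a nitrate transporter (BM177075.1_485, at least 13.4-fold) and a carbonic anhydrase (GMFL01-22-L20-R_541, at least 211-fold). The nitrate transporter homolog that rose with each single microbe (BQ613046.1_186) was higher by 2.73 ± 0.69 (adjusted p = 0.018; 0.080 with median scaling). The leghemoglobin probe GMFL01-11-O02-R_23 did not pass with quantile normalization (adjusted p = 0.067), median scaling (0.057) or the scan as a block (0.099). Nodulin-27 (GMFL01-25-E11-F_6, 3.31 ± 0.94), nodulin 6l (AI988327.1_406, 3.29 ± 0.88) and GmN70 (GMFL01-18-B16-R_471, 2.42 ± 0.69) rose, with rhizobium well above background on 2 of 3 arrays each, the first and the second not with median scaling (adjusted p = 0.071 and 0.063), while nodulin 22 (BE611203.1_357) fell at least 2.50-fold.

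Of 9 leghemoglobin probes 2 rose with the fungus in nodulated roots (mean 1.46, camera adjusted p = 0.047) and of 58 nodulins 4 rose and 3 fell (0.72, 0.00064). Of 40 fatty acid synthesis probes 12 rose and 4 fell (0.56, 6.3e-05), with biotin carboxylase accC-3 (CX704253.1_602) up by 3.32 ± 0.24. Of 83 isoflavonoid and phenylpropanoid probes 4 rose and 21 fell (4 and 24 adjusted over the list alone; mean -0.80, adjusted p = 0.020), among them the reductase of deoxychalcone synthesis (AW102116.1_695, at least 3.51-fold). Photosynthesis (1 rise, 46 falls, mean -1.24, adjusted p = 2.2e-05) and seed storage (1 rise, 18 falls, -1.28, 0.0029) were lower, the latter with a 7S globulin down at least 5.72-fold (BG352733.1_580) and a 2S albumin at -2.88 ± 0.29 (AW433006.1_359, dual well above background on 2 of 3 arrays). Ribosomal proteins were higher relative to other probes with a mean of -0.14, a median of 0.32, 25 rises and 65 falls (adjusted p = 0.0015). Each of these had adjusted p = 0.98 with an estimated correlation. With the scan as a block nodulins (1.09, adjusted p = 0.00014), fatty acid synthesis (0.52, 0.012), isoflavonoids (-0.96, 0.0002), photosynthesis (-0.92, 0.012) and seed storage (-1.03, 0.029) passed, and leghemoglobins (1.26, 0.21) and ribosomal proteins (-0.16, 0.095) did not. Within scan 3, with 1 rhizobium array, the means were 1.52 for nodulins, -0.84 for isoflavonoids, 1.72 for leghemoglobins and 0.59 for fatty acid synthesis. They were -0.14 for ribosomal proteins, -0.59 for photosynthesis and -0.68 for seed storage. With 1 array in a group only the means are given, and they back no list call. Leghemoglobins did not pass with quantile normalization either (1.56, adjusted p = 0.20), nor isoflavonoids under normexp (-0.53, adjusted p = 0.22).

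In dual against rhizobium roots 7259 of 33404 probes passed in limma, 1676 higher and 5583 lower, and 37.5% of probes did not overlap (10% by chance). Falls made up 86.7% of the calls among the 11136 probes with the lowest signal and 58.3% among the 11135 brightest. Quantile normalization gave 6825 calls (2956 higher, 3869 lower) and median scaling 6118 (2451 higher, 3667 lower). The median of all probes was -0.14, -0.02 and 0.11. Blocking on the scan left 7080 (2591 higher, 4489 lower). Within scan 3, which holds 1 rhizobium array and the 3 dual arrays, 7769 passed, 4291 higher and 3478 lower. That array is rhizobium 3, which stands apart on the second principal component.

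The comparison of dual with AM roots asks what the rhizobium adds to roots that hold the fungus, and nodule transcripts led it. Leghemoglobin (GMFL01-02-G04-R_389) rose at least 1140-fold (adjusted p = 0.0050), nodulin C51 (GMFL01-10-C23-R_647) at least 537-fold (adjusted p = 0.00062), a nodulin (GMFL01-19-F21-R_322) at least 485-fold (adjusted p = 0.0089) and nod24 (CO978758.1_684) by 11.53 ± 1.94 (adjusted p = 0.033, AM well above background on 1 of 3 arrays). Nodulin-26b (GMFL01-22-I17-R_468) rose at least 309-fold, nodulin E27 (GMFL01-22-I02-R_554) at least 257-fold, GmN93 (GMFL01-21-A17-R_103) at least 140-fold and nodulin-27 (GMFL01-07-I03-R_141) by 9.90 ± 0.95, AM well above background on 1 of 3 arrays. Beyond nodulins, a predicted membrane transporter (GMFL01-08-O20-R_327) rose at least 77.6-fold, an IAA-amino acid hydrolase (GMFL01-13-L15-R_397), which frees the hormone auxin, at least 77.3-fold, and peroxidase Prx4 (AI973735.1_417) at least 61.2-fold. Glutamine synthetase (GMFL01-09-P04-R_499) rose by 2.28 ± 0.39 (adjusted p = 0.033), and a ferric reductase homolog (BG511181.1_363) fell by 2.47 ± 0.44 (adjusted p = 0.040).

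Smaller rises with the rhizobium in these roots were acyl-ACP desaturases (GMFL01-25-C19-R_419, 4.09 ± 0.67, and BU927132.1_512, 3.76 ± 0.50), beta-amylase (GMFL01-16-M17-R_701, 3.04 ± 0.33), which breaks down starch, lipoxygenases (GMFL01-02-K07-R_668, 2.69 ± 0.46, and lox7, GMFL01-10-E03-R_618, 1.94 ± 0.35) and the nodule inception homolog (CO980521.1_545, at least 6.56-fold). Smaller falls were root phototropism protein 2 (CO981753.1_674, -1.75 ± 0.26), a DnaJ chaperone (GMFL01-13-H23-F_774, -1.70 ± 0.31), a malate transporter homolog (GMFL01-22-H01-R_507, -1.55 ± 0.28), a galactosyltransferase (BE659691.1_574, -1.38 ± 0.21) and an expansin-like protein (GMFL01-19-H01-R_202, -1.21 ± 0.21). Several of these calls lay close to the threshold. With median scaling nod24 (12.30, adjusted p = 0.060), the IAA-amino acid hydrolase (0.061), lox7 (1.90, 0.078), the DnaJ chaperone (-1.75, 0.059) and the galactosyltransferase (-1.42, 0.055) did not pass, and with quantile normalization the nodule inception homolog (0.065) and the malate transporter (-1.50, 0.071) did not. With the scan as a block nodulin C51 (adjusted p = 0.028), nodulin-27 (9.64, 0.037), GmN93 (0.044) and lipoxygenase GMFL01-02-K07-R_668 (3.22, 0.033) passed. Leghemoglobin GMFL01-02-G04-R_389 (0.051), nod24 (10.77, 0.17), glutamine synthetase (2.49, 0.17), the ferric reductase homolog (-2.58, 0.19) and the other genes named for this comparison kept their direction and did not pass.

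Of 9 leghemoglobin probes 6 rose and of 58 nodulins 17 rose in dual against AM roots, with none lower and means of 6.71 and 2.29 (camera adjusted p = 6.9e-15 and 3.6e-11). Of 75 jasmonate and lipoxygenase probes 2 rose (mean 0.33, adjusted p = 0.0063), and of 10 vegetative storage probes 2 rose (1.10, 0.0018), one being VSP27 (BF423527.1_329), a storage protein of vegetative tissue, at least 1.90-fold. With none past the test singly, 29 purine and ureide synthesis probes (mean 0.28, adjusted p = 0.014), whose pathway makes the transport form of fixed nitrogen, were higher as a group. So were 7 ammonium transporter probes (0.53, 0.033), 111 cell cycle probes (0.22, 0.044) and 427 ribosomal protein probes (0.21, 1.5e-05). All had adjusted p = 0.98 with an estimated correlation. In the scan-block fit leghemoglobins (6.52), nodulins (2.65), purine and ureide synthesis (0.38), jasmonate (0.42), cell cycle (0.39) and vegetative storage (1.03) passed, and ammonium transporters (0.35, adjusted p = 0.35) and ribosomal proteins (0.19, 0.059) did not. Within scan 3, with 1 AM array, the means were 6.05 for leghemoglobins, 2.22 for nodulins, 0.27 for jasmonate and 0.16 for ribosomal proteins. They were 0.16 for purine and ureide synthesis, 0.46 for ammonium transporters, 0.10 for cell cycle and 0.84 for vegetative storage. With 1 array in a group only the means are given, and they back no list call. Cell cycle had a mean of -0.03 under normexp and adjusted p = 0.050 with the replicate number as a block, ammonium transporters had 0.059 with quantile normalization, and nodulins did not pass on probes well above background on every array (mean 0.31, adjusted p = 0.40).

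In dual against AM roots 177 of 33404 probes passed in limma, 157 higher and 20 lower, with 3424 at an unadjusted p under 0.05. The arrays did not overlap for 21.8% of probes, where chance gives 10%, and the median of all probes was -0.01. Blocking on the scan left 38 (37 higher, 1 lower). Within scan 3, with 1 AM array, none did. The count was 62 without AM 1, 77 without AM 2, 72 without dual 2, 95 without dual 3 and 278 without rhizobium 3.

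The interaction, dual minus rhizobium minus AM plus control, asks whether the joint effect differs from the sum of the single ones. A leghemoglobin probe (GMFL01-23-B02-R_31) had an interaction of 6.37 ± 0.66 (adjusted p = 0.013) and nodulin-27 (GMFL01-14-A14-R_1) of 5.87 ± 0.67 (adjusted p = 0.014), so their difference with rhizobium was larger where the fungus was present. Without it the differences were 1.96 and 1.63, neither called (adjusted p = 0.12 and 0.17), and in AM roots no array was above background for either probe and both lay at the floor of 0.01, so the size of the interaction depends on that floor. Values for VSP27 (BF423527.1_329, 3.18 ± 0.45, adjusted p = 0.048), below detection in AM roots, and the TINY-like factor (CX710923.1_596, 2.91 ± 0.29, adjusted p = 0.013), at the floor in rhizobium roots, were also positive, with a size set by the floor. The AAA-type ATPase (AW185464.1_481, 3.41 ± 0.24, adjusted p = 0.0012) was below detection in rhizobium, AM and dual roots, so its value is the distance of control from the floor and shows no departure from the sum. The nitrate transporter homolog (BQ613046.1_186) lay below it by -7.15 ± 0.98 (adjusted p = 0.042), having risen with each microbe alone and not by their sum with both. Control was well above background for it on 1 of 3 arrays, so the size of this value depends on the floor as well. Leghemoglobins (mean 4.13, camera adjusted p = 1.5e-06, 1 of 9 past the test), nodulins (1.29, 0.0051, 1 of 58), jasmonate and lipoxygenase (0.75, 0.0018, 0 of 75) and seed storage (0.72, 0.017, 1 of 34) were higher as lists, each at adjusted p = 0.98 with an estimated correlation. The median interaction over the 11136 probes with the lowest signal was 0.73, and over the 11135 brightest it was -0.15. Most seed storage probes were dim, and camera set the list against probes of all signal levels. The seed storage mean of 0.72 therefore cannot be told from a shift shared by dim probes. For nodulins and for jasmonate and lipoxygenase the part played by signal level was not tested. In the scan-block fit leghemoglobins (3.20, adjusted p = 0.0062) and seed storage (1.01, 0.012) passed, and nodulins (1.14, 0.068) and jasmonate (0.67, 0.21) did not. Nodulins did not pass without control 3 either (adjusted p = 0.057). The mean of nodulins was -0.02 on probes well above background on every array and that of seed storage -0.55 under normexp. The ATPase and TINY-like values also turned negative under normexp, to -0.35 and -0.30, and did not pass with quantile normalization (adjusted p = 0.11 and 0.59). The nitrate transporter did not pass with median scaling (-8.77, adjusted p = 0.096) or the scan as a block (-8.08, adjusted p = 0.16). With the replicate number as a block it did not pass (adjusted p = 0.067), nor did nodulin-27 (0.057) or VSP27 (0.10).

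For the interaction 22 of 33404 probes passed in limma, 19 higher and 3 lower, with 2872 at an unadjusted p under 0.05. Of these calls 18 lay among the 11136 probes with the lowest signal, 17 higher and 1 lower. The 11135 brightest probes held 2 calls, each lower. The median of all probes was 0.17, 0.04 with quantile normalization and -0.07 with median scaling. Quantile normalization left 7 calls (3 higher, 4 lower), the scan as a block 3, all higher, and the replicate number as a block 8 (7 higher, 1 lower). The count was 13 without control 1, 14 without control 2, 13 without control 3, 3 without AM 1 or AM 2 and 300 without rhizobium 1. No scan holds all 4 groups, so no value within a scan can be given.

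The responses to the single microbes overlapped in part. Of the 120 probes called with rhizobium, 11 were also called higher and 58 lower with the fungus, and 7 were called in opposite directions. Independent lists of these sizes would share 1.57 higher and 27.4 lower. Both comparisons use the same 3 control arrays: in 20 simulations of unchanged groups with shared controls no probe was shared, as unchanged groups are expected to give almost no calls, so this value says nothing about the shared calls. In the simulations the correlation of fold changes across probes was 0.50 against 0.26 observed, and the covariance 0.11 against 0.25, a difference of 0.14. The 3 controls cannot be split into sets of at least 2 arrays each, so part of the shared calls may come from sharing them. The overlap was 22 with quantile normalization (17 higher and 5 lower, so the excess of shared falls turned round), 4 with the scan as a block (all lower), and without 1 array 20 (control 1), 32 (control 2), 40 (AM 1), 38 (AM 2), 36 (dual 1), 43 (dual 2) and 533 (rhizobium 1).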

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

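The tests of nodule transcripts on the control 3 array, of the dim end of the signal range, of the nodule interaction with the offset or floor of 0.25, and of that interaction over probes chosen by the mean rhizobium effect or over all list members were chosen after the results were seen; the tests by scan session, of the interaction without control 3 and of other groupings were set before.

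The effect of rhizobium differed between roots with and without the AM fungus by the interaction test for 22 probes, at limma adjusted p under 0.05. The named ones were a leghemoglobin (GMFL01-23-B02-R_31, 6.37), nodulin-27 (GMFL01-14-A14-R_1, 5.87), an AAA-type ATPase (AW185464.1_481, 3.41), VSP27 (BF423527.1_329, 3.18), a TINY-like factor (CX710923.1_596, 2.91) and a nitrate transporter homolog (BQ613046.1_186, -7.15). The ATPase was below detection in rhizobium, AM and dual roots, so its value was fixed by the floor and shows no departure from the sum. The TINY-like factor lay at the floor in rhizobium roots, and the leghemoglobin, nodulin-27 and VSP27 were below detection in AM roots, so the sizes of these values are set by the floor. The nitrate transporter homolog was well above background on 1 of 3 control arrays, so the size of its value depends on the floor too. Among the lists the difference was tested by camera for leghemoglobins (mean 4.13), nodulins (1.29), jasmonate and lipoxygenase (0.75) and seed storage (0.72), none of which passed with an estimated correlation (adjusted p = 0.98). Over the 11136 probes with the lowest signal, which held 18 of the 22 calls, the median interaction was 0.73. The seed storage mean cannot be told from that shift, as most probes of the list were dim. Of 100 groupings of the 12 arrays, the real one included, 3 gave at least 22 calls. The other groupings mix arrays with and without the fungus, whose large effect then enters the spread, so they say nothing about chance for this count. The highest other grouping gave 1958, and leaving out 1 array moved the count from 3 (without AM 1) to 300 (without rhizobium 1).

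Nodule transcripts stood higher on 1 control array than on the others. Over 23 nodule probes control 3 was above both other controls on 19 (median 2.16 over their mean) and below all 3 rhizobium arrays on 21, at a median of 17.2% of the rhizobium level (quartiles 6.55 and 24.1). A swap with a rhizobium array is argued against, since the lowest rhizobium array stood a median of 3.59 above the higher of the other controls, with no rhizobium array out of place. RNA from a dual sample is argued against as well, for 51 probes strongly raised by the fungus in AM against control and dual against rhizobium roots. They lay a median of 2.41 log2 units under the level that source would bring (-2.41, quartiles -3.14 and -1.52). Control 3 was part of the control group in that choice, which favours probes low on that array, so the gap may be overstated. A single wrong label, with an inoculated but poorly nodulated root filed as control (-1.88 SD from the rhizobium mean), and RNA from a rhizobium sample or nodules on the control roots themselves (interquartile range of the share 1.04 log2 units) stay open and cannot be told apart, because 1 array holds the pattern and no other file records nodule numbers. Over the kept probes control 3 correlated with rhizobium 1 at 0.969, above control 1 (0.956) and control 2 (0.946). With rhizobium 2 and 3 it correlated lower, at 0.925 and 0.912. These values do not choose among the open sources.

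Called falls outnumbered called rises with the fungus in the main scaling (9138 and 2629), and with median scaling rises outnumbered falls (6689 and 5430). The scan session stays open: within scan 2 64.7% of all probes were lower on the 2 AM arrays than on control 1, and the scan as a block gave 1831 rises and 5667 falls, but control 1 is the only control scanned with AM arrays, and the share among called falls, also set as a test, was fixed by the choice of those probes. A difference between arrays in signal at the dim end may contribute and stays open. Among the brightest 33.3% of probes 35.4% of calls were falls, against 95.2% among the dimmest, and a floor of 0.25 brought rises and falls to 1986 and 1815, yet a loss of many weakly expressed transcripts would give the same picture. The AM arrays had 62.6% to 65.4% of probes well above background and the control arrays 80.1% to 86.6%, in every array of both groups, so background and treatment cannot be told apart here.

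The nodule probes responded more to rhizobium with the fungus than without, by a median interaction of 4.39 over 23 probes picked by their rise in dual against AM roots, which is part of the interaction. The nodule transcripts on control 3 as the whole cause are argued against, since without that array the median was 3.85 (quartiles 2.32 and 4.76). With an offset of 0.25 and without control 3 the median was 1.85 (quartiles 1.5 and 2.39), and 1.77 with a floor of 0.25 instead, so both corrections lowered it. Both also bring control 1 and 2 (array medians of -3.73 and -3.85 in log2) and the AM arrays close together, as these lie under 0.25. What remains is mostly the rise of dual over rhizobium roots (median 2.07 in the main values). The floor and the background on the AM arrays as the whole cause therefore stay open. Picking list members by the mean effect of rhizobium over both backgrounds gave the same 23 probes and so the same medians. That choice would be independent of the interaction only if the groups spread alike. The SD of the array medians was 1.93 for control and 0.81 for rhizobium, and the floor in AM roots enters both, so the medians may still owe part of their size to the choice. Over all 67 members the median was 0.81 (0.77 without control 3, then 0.41 with the offset and 0.15 with the floor). A larger nodule mass or activity with the fungus is a hypothesis that these data cannot test, as the files give no nodule counts.

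Splits of the 6 arrays of 2 groups are too few (10) for a share under 0.05. In each comparison 1 split, the real one, gave as many calls: with rhizobium against control 120 and the highest other split 3, with AM against control 11767 and 0, with dual against control 11798 and 0, with dual against rhizobium 7259 and 11, and with dual against AM 177 and 1. Each other split mixes arrays of the 2 groups, so any real difference between them enters the spread and lowers its count. The low counts of the other splits therefore say nothing about chance. Among the splits that part all 3 numbered pairs, the highest other gave 3 for rhizobium against control and 0 for dual against control, and the remaining splits part 1 pair.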

How the results depend on the processing

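Fits with a floor or offset of 0.25, each with or without control 3, with quantile normalization of kept probes alone, and within scans were chosen after the data were seen, as were the scan block for the overlap and for gene lists and the strict filter for gene lists; the rest were planned. The cause of a change was not tested unless stated. The slide could not serve as a block, since each slide held 1 array, so the fit planned with it was not run. No fit within a scan can give dual against control or the interaction.

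Calls for rhizobium against control (120 in the main analysis) were 4 with normexp, 40 with quantile normalization, 57 with median scaling, 409 without a filter, 0 with the strict filter (limma, 6036 at an unadjusted p under 0.05 among all kept probes), 40 at adjusted p under 0.01, 73 with a trend, 0 in a separate fit of the 2 groups, 191 with the replicate block, 4 with the scan block, 17 with the floor, 2 with the offset, 0 within scan 2, 1131 with the floor and 519 with the offset without control 3. Without 1 array they ran from 40 (control 1) to 1118 (rhizobium 1).

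For AM against control (11767) they were 6227 with normexp, 5468 with the strict filter (fewer probes tested), 7307 at adjusted p under 0.01, 7498 with the scan block, 6847 within scan 2, 3801 with the floor and 5148 with the floor without control 3; without 1 array 8575 (AM 1) to 14125 (rhizobium 3). For dual against control (11798) they were 5484 with the strict filter, 6981 at adjusted p under 0.01, 4363 with the scan block, 3728 with the floor and 5449 with the floor without control 3; without 1 array 8013 (control 1) to 14291 (rhizobium 3). For dual against rhizobium (7259) they were 13547 with normexp, 2579 with the strict filter, 4151 at adjusted p under 0.01, 1580 with the floor and 1953 with the floor without control 3; without 1 array 5235 (dual 2) to 8407 (rhizobium 3). For dual against AM (177) they were 63 with the strict filter, 69 at adjusted p under 0.01, 38 with the scan block, 97 with the floor, 0 within scan 3 (limma, 3424 unadjusted over all arrays) and 48 with the floor without control 3; without 1 array 62 (AM 1) to 278 (rhizobium 3).

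Interaction calls (22) were 1 with normexp, 7 with quantile normalization and 4 when it used kept probes alone, 103 without a filter, 0 with the strict filter (limma, 2872 unadjusted among all kept probes), 2 at adjusted p under 0.01, 5 with a trend, 8 with the replicate block, 3 with the scan block, 9 with the floor, 2 with the offset, 431 with the floor and 0 with the offset without control 3; without 1 array 3 (AM 1) to 300 (rhizobium 1). The overlap of the 2 single responses (69) was 3 with normexp, 22 with quantile normalization, 311 without a filter, 22 at adjusted p under 0.01, 108 with the replicate block, 4 with the scan block, 15 with the floor, 2 with the offset and 0 within scan 2, where no probe passed for rhizobium; without 1 array 20 (control 1) to 533 (rhizobium 1). Called lists (38) were 19 with the strict filter, 24 with the floor without control 3, 0 with the estimated correlation and 60 with fry. Of the 38 lists called in the main analysis fry kept 19, 17 lost their call and 2 pointed the other way. Those lost included leghemoglobins (fry adjusted p = 0.066) and nodulins (0.27) for rhizobium against control. Without 1 array the called lists numbered 33 (dual 2) to 42 (control 1).

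Of the calls in the main analysis 100% kept their direction with the scan block for rhizobium against control and AM against control and 99.9% for dual against control. For the rhizobium and AM calls this was largely fixed by their choice. The arrays did not overlap for 120 of the 120 and 11570 of the 11767, and the blocked fit uses the same arrays. Quantile normalization shared 7492 of the 11767 AM calls, 7573 of the 11798 dual against control calls and 5371 of the 7259 dual against rhizobium calls, and 97.2%, 97.6% and 99.9% of these calls kept their direction. Under normexp 50% of the rhizobium calls and 31.8% of the interaction calls did.

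Over the 186 named values, none lost its call with uneven spots kept, the deposited table or a fold of at least 2. Those that lost it numbered 29 with quantile normalization, 26 with median scaling, 14 without a filter, 32 with normexp (besides the called values that changed sign, given below), 15 with the replicate block, 67 with the scan block, 90 with the floor, 33 with the offset and 47 at adjusted p under 0.01. Probes dim on all arrays become constant under the floor, which by construction removes them. The deposited table holds the main values with some replicates reordered within groups, so its fit all but repeats the main one. Named values were picked for large changes, so a fold of at least 2 could remove few of them.

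Few named genes changed sign. Under normexp these were, for rhizobium against control, CX710923.1_596 (0.06), AW756565.1_386 (0.02), CK605689.1_715 (0.04) and BE658656.1_70 (-0.04, not called), and for the interaction AW185464.1_481 (-0.35), CX710923.1_596 (-0.30) and BE824280.1_451 (-0.23). Under median scaling CO982431.1_713 turned to 0.03 for rhizobium against control, and with the scan block GMFL01-24-N24-R_381 to 0.31 for dual against AM, neither called before. Among list means photosynthesis for rhizobium against control turned to 0.11 with normexp and 0.04 with quantile normalization of kept probes, and seed storage to 0.11 with normexp. Seed storage turned to 0.16 with the floor (0.13 without control 3) for AM against control, to 0.04 (0.01 without control 3) for dual against control, to 0.08 (0.08) for dual against rhizobium, and to -0.55 with normexp for the interaction. With a floor of 0.25 the seed storage interaction was -0.08. The nodulin interaction turned to -0.02 with the strict filter. Ribosomal proteins and cell cycle, called higher relative to other probes with means near 0, changed the sign of the mean under several settings while camera pointed up in each. Examples are ribosomal proteins for AM against control (-0.32, then 0.01 with median scaling), for dual against control (-0.11, then 0.15 with the scan block), for dual against rhizobium (-0.14, then 0.06 with quantile normalization) and for rhizobium against control (0.04, then -0.03 without a filter). Cell cycle moved from -0.19 to 0.20 with the scan block for dual against control and from 0.22 to -0.03 with normexp for dual against AM. Fry pointed down for ribosomal proteins with AM against control (mean -0.32) and for cell cycle with dual against control (mean -0.19), the sign of the means.

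Signal over background limits the dim end most on rhizobium 3, with 11% of kept probes at the floor, and then on the AM and dual arrays with 4.6% to 7%, against 0.3% to 0.73% on control arrays.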

Other observations

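The list tests below were planned, and the cytokinin probes and the values of the last 2 paragraphs were chosen after the results were seen.

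The remaining lists did not pass camera with AM against control (rises and falls of tested probes, limma and camera adjusted p). Carbon supply to nodules had 13 rises and 21 falls of 79 (adjusted p = 0.65), the carotenoid and strigolactone pathway 5 and 11 of 29 (0.81), protease inhibitors 3 and 16 of 29 (0.096), proteases 15 and 39 of 172 (0.73), defence 7 and 35 of 112 (0.56) and class III peroxidases 3 and 31 of 88 (0.38). Aquaporins had 6 and 11 of 44 (0.51), sugar transport 3 and 6 of 32 (0.70), starch metabolism 6 and 21 of 68 (0.86), auxin 6 and 49 of 123 (0.30), ethylene 7 and 18 of 65 (0.95) and gibberellin 5 and 2 of 14 (0.11). Iron and nicotianamine had 2 and 10 of 30 (0.70), lectins 0 and 4 of 12 (0.57), heat shock 13 and 32 of 119 (0.48) and dehydration 0 and 5 of 10 (0.56). Isoflavonoid and phenylpropanoid probes had 3 and 27 of 83 (0.13), vegetative storage 0 and 7 of 10 (0.11), ammonium assimilation 3 and 15 of 50 (0.65), purine and ureide synthesis 2 and 7 of 29 (0.68), symbiosis signalling 4 and 6 of 24 (0.32) and cell cycle 19 and 29 of 111 (0.29). Members with the fungus included a starch branching enzyme (AW508491.1_313, 4.40 ± 0.47), an alpha-amylase (GMFL01-12-K20-R_189, 5.70 ± 0.50), ACC oxidase of ethylene synthesis (GMFL01-04-M14-R_311, 4.01 ± 0.52), gibberellin 2-oxidase (BI969604.1_638, 2.09 ± 0.31) and gibberellin 20-oxidase (CA801318.1_559, 1.97 ± 0.22). Phytoene desaturase (AW733937.1_531) was at least 3.29-fold lower, the lectin Le2 (GMFL01-20-M10-R_482) at least 7.94-fold lower and the heat shock protein Hsp22.3 (CX702057.1_769) at least 8.31-fold higher.

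Cytokinin had 4 probes, too few for a list test. A cytokinin-binding protein (AW309358.1_558) rose with the fungus by 2.13 (limma adjusted p = 0.0027), and a cytokinin oxidase (BU926889.1_465) was lower (adjusted p = 4.0e-05).

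The photosynthesis and seed storage lists stand for green tissue and cotyledons, tissues other than the sampled roots. Both were lower in AM and dual roots than in control roots, with means of -1.87 and -2.0 for AM and -1.81 and -2.08 for dual, and most of their probes were dim. With an estimated correlation neither list passed (adjusted p = 0.98), and with a floor of 0.25 the means were -0.03 and 0.16 for AM and -0.06 and 0.04 for dual. No pair of arrays shared more than 0.0024% of its values, and saturated spots numbered 4 to 12 per array.

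On the 23 nodule probes, picked by their rise in dual against AM roots, dual roots were above rhizobium roots by a median of 2.07 (22 of 23 higher, 12 above all rhizobium arrays, and 2.52 against the 1 rhizobium array of scan 3). An exact test of the array medians gave p = 0.1, the smallest that 3 against 3 arrays can give. The choice of probes favours high values on the same dual arrays, so this p-value is biased low and decides nothing. Over all list members the median was 2.07 for 9 leghemoglobin probes (2 rises) and 0.76 for 58 nodulin probes (4 rises and 3 falls).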
